A study of Homo sapiens with 17 samples.

How the data were processed

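Total RNA from normal human bronchial epithelial cells was measured on 17 single-channel 3′ expression arrays, 1 array for each stimulus and time. The stimuli were none (control), pressure, AG1478, pressure with AG1478, and HBEGF. Control and AG1478 were measured at 0, 1, 3 and 8 h, and the other 3 stimuli at 1, 3 and 8 h. The labels name 2 hybridization batches: batch 2 held 4 arrays (control at 0 and 1 h, pressure at 1 h, pressure with AG1478 at 8 h) and batch 1 held the other 13. No array was left out of the main comparisons, and every column of the deposited table belonged to 1 of the 17 arrays.

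The deposited values were log2 expression values, 1 for each of 22283 probe sets, summarised by the authors with RMA (robust multi-array average, which corrects background, equalises the distributions of the arrays and summarises each probe set), per the submitters' processing notes. That the scale is log2 was inferred from the values, which ran from 3.25 to 14.4 with array medians between 6.19 and 6.31. The version of RMA, the software and whether any adjustment for batch was made are not given in the sources used here. RMA makes the distributions of the arrays alike, so a change shared by most genes would not be seen. Precision is limited by the number of arrays.

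Probe sets were given gene symbols from the platform's annotation, and symbols were brought up to date through Entrez gene identifiers in a RefSeq gene table. Of the 22283 probe sets, 19071 had 1 symbol (19059 of them matched by identifier), 1043 had several symbols and were left out, and 2169 had none. The probe sets with 1 symbol gave 11963 genes, 4310 of which had more than 1 probe set. A gene was represented by its probe set with the highest mean over the 17 arrays. The dimmest 40% of the genes by that mean (4785 genes) were left out, which left 7178 genes with means of at least 6.23. The 68 control probe sets of the array were used only to compare signal from the 3′ and 5′ ends of ACTB and GAPDH and to record the signal of Alu sequences.

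Comparisons were made with limma 3.58.1 in R 4.3.3. A single linear model with terms for stimulus, time point and hybridization batch was fitted to all 17 arrays, and 6 contrasts were tested with moderated statistics (eBayes): pressure against control, pressure with AG1478 against AG1478, the difference of those 2 effects, AG1478 against control, HBEGF against control, and HBEGF against pressure. A further model added, for each stimulus, a slope on the log2 of hours plus 1, and the slope of pressure minus that of control was tested. Because no stimulus and time was replicated, the residual spread (8 degrees of freedom, or 4 with slopes) is the departure of single arrays from additive effects of stimulus, time and batch. Fitted values are log2 differences averaged over times, with the model's standard error (SE). P-values were adjusted by the Benjamini-Hochberg method over the 7178 genes, with a threshold of 0.05. Batch was a term in the model, so fitted differences are adjusted for it.

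A set of 24 gene lists with 422 genes (355 on the array, 283 tested) was tested with limma's camera with a preset correlation of 0.01, and again with a correlation estimated for each list. limma's rotation test fry was run on the same lists as an alternative. P-values were adjusted over the 24 lists of a comparison. The lists were EGFR ligands, EGFR family receptors and sheddases, immediate early genes, ERK feedback genes, proteolysis and matrix remodelling, inflammatory cytokines and NF-kB targets, TGF-beta and BMP targets, YAP/TAZ targets, SRF and actin cytoskeleton genes, cholesterol biosynthesis, cell cycle, hypoxia and glycolysis, heat shock response, unfolded protein and integrated stress response, NRF2 targets, aryl hydrocarbon receptor targets, FOXO targets, interferon-stimulated genes, squamous differentiation, and markers of ciliated, secretory and basal cells, of fibroblasts, and of endothelial cells and leukocytes. The lists, the tests, the thresholds and the alternatives in the closing section, except those named there as chosen later, were fixed before the data were examined.

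Differences between single arrays of the same time are given as values with no test. Genes with a difference of at least 1 log2 unit (2-fold) were counted, and the median difference of each list was placed among those of 10000 random lists matched for expression. Where 2 arrays came from different batches, the fitted batch effect was also subtracted. That effect was fitted with the same arrays, on the assumption of 1 constant effect of each stimulus over time. Its removal can draw a difference toward the fitted effect, so such values are not an independent time point. The share of the pressure response kept under AG1478 is the slope through 0 of 1 difference on the other at 3 h, over genes picked for a 2-fold difference at 8 h, with a 95% interval from 2000 bootstrap draws over genes. The responses to HBEGF and pressure were correlated across genes between unmatched times, which share no control array.

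Genes were named by a rule set in advance. Per contrast it took up to 10 genes in each direction that passed limma and whose single-array differences had the same sign at 1, 3 and 8 h, then up to 5 per direction that were 2-fold in the same direction at all 3 times. Per time point of pressure, HBEGF and pressure under AG1478 it took the 5 highest and the 5 lowest differences, and per list up to 4 members with the smallest p. EGFR and HBEGF were always named. Exceptions, chosen after their values were seen, are CYP1B1, list members beyond the first 4 that passed when adjusted over the list alone, genes with the highest and lowest differences after removal of the batch effect, other values of named genes with the batch effect removed, CYP1A1, and DUSP6 under AG1478.

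The scripts were tested on simulated data with the real means and spreads, in which 200 of 7178 genes were changed. With changes of 1 log2 unit, limma recovered 95% of the changed genes for pressure against control, 94.5% for pressure under AG1478, 88.5% for the difference of those effects, 97.5% for AG1478 against control, 96.5% for HBEGF against control, 97.5% for HBEGF against pressure, and 93% for the time trend. A list of 18 genes shifted by 0.3 was called in each comparison with the preset correlation, and in each but the time trend with an estimated one. A simulated share kept of 0.5 was returned as 0.496, and 2 unrelated responses gave a correlation of 0.004. The simulated changes followed the form of the fitted model, and noise was drawn independently for each gene. The recovery rates therefore do not cover responses that vary between times in other ways. The simulation also gives no rate of false list calls among correlated genes.

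Alternatives changed the batch term, the filter, the choice of probe set, the centring of arrays, the fold and the list test, and left out arrays or time points. Figures were drawn with matplotlib.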

Results

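Gene expression was measured in normal human bronchial epithelial cells, the primary lining cells of the airway, under 5 conditions over 8 h. Unstimulated control cells were measured at 0, 1, 3 and 8 h, and so were cells given AG1478, a small-molecule inhibitor of the EGFR kinase. Cells under pressure, cells under pressure with AG1478, and cells given HBEGF, a ligand of EGFR, were measured at 1, 3 and 8 h each. Each of these 17 combinations was measured on 1 array, so there were no replicates. Every p-value here measures departures of arrays from additive effects of stimulus, time and hybridization batch in limma, not a spread between replicates. The strength of the pressure and the concentrations of AG1478 and HBEGF are not given in the sources used here. The arrays had median log2 values of 6.19 to 6.31 over all probe sets, and 7178 genes were tested.

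The arrays separated first by hybridization batch. Batch 2 held control at 0 and 1 h, pressure at 1 h and pressure with AG1478 at 8 h. These 4 arrays had scores of -24.1 to -33.8 on the first principal component (58.4% of the variance), against 0.70 to 23.9 for the other 13 arrays. The median correlation between arrays was 0.982 within a batch and 0.934 across batches. limma called 3213 genes between the batches, 1703 higher and 1510 lower in batch 2, with 248 of them over 2-fold. The pressure and control pairs of 1, 3 and 8 h each lay within 1 batch. The AG1478 and control pairs crossed batches at 0 and 1 h, the HBEGF and control pair at 1 h, and the pressure with AG1478 and AG1478 pair at 8 h. Signal from the 3′ end of ACTB exceeded that from its 5′ end by 1.69 log2 units in control at 0 h, 0.96 in control at 1 h, 0.72 in pressure at 1 h, 0.70 in AG1478 at 3 h, 0.24 in AG1478 at 8 h and 0.21 in pressure with AG1478 at 8 h. It was below the 5′ signal in the other 11 arrays. For GAPDH the difference was highest in control at 0 h (0.79), AG1478 at 8 h (0.43) and AG1478 at 3 h (0.29). The signal of Alu sequences was 13.46 to 13.49 in batch 2 and 12.89 to 13.24 in batch 1. The array of pressure with AG1478 at 3 h had the narrowest spread of values (SD 1.86, against up to 1.96) and the highest score on the second component (19.7).

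**Figure D1:**
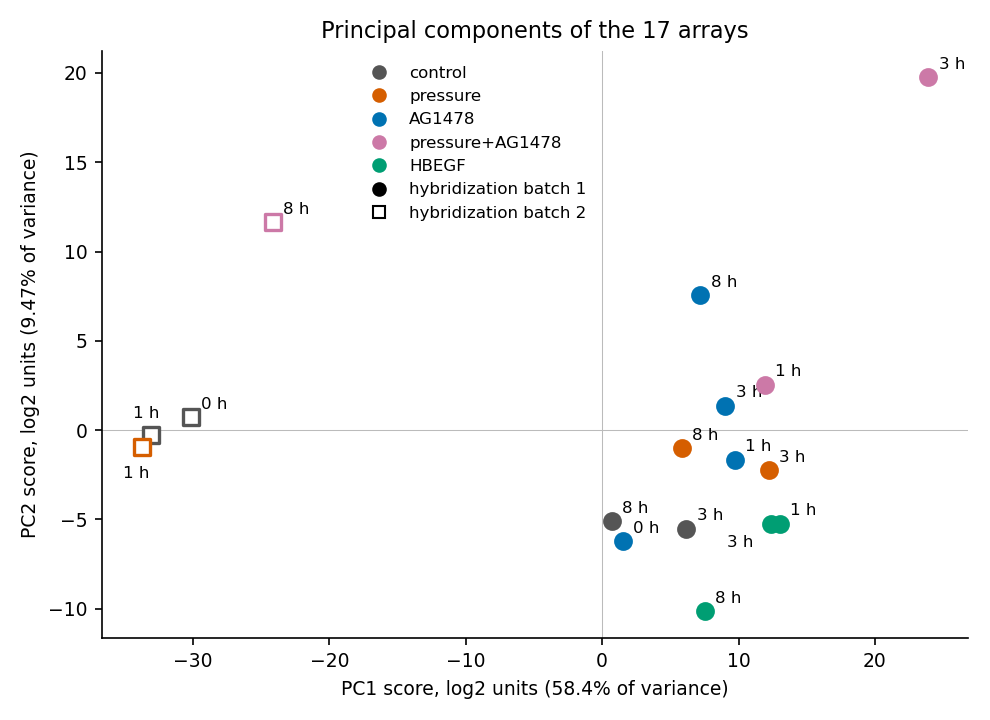
Scores of the 17 arrays on the first 2 principal components in log2 units, coloured by stimulus, with circles for hybridization batch 1 and squares for batch 2, and labelled by time. The 4 arrays of batch 2 lie at scores of -24.1 to -33.8 on the first component, and the array of pressure with AG1478 at 3 h lies highest on the second (19.7).

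Pressure against control asked which genes respond to the mechanical stimulus. Genes of the SRF and actin cytoskeleton list, which are targets of serum response factor and parts of the contractile machinery, rose as a group. Their fitted log2 differences averaged 0.38 (SD 0.31) and 17 of 18 were positive (camera adjusted p = 2.17e-14, and adjusted p = 0.0348 with an estimated correlation). As a group they were also higher in batch 1 than in batch 2. The pressure arrays of 3 and 8 h lay further from batch 2 than their controls on the first principal component. Whether this adds to the rise was not tested. The myosin light chain gene MYL9 had a fitted difference of 1.26 (SE 0.33), the actin-binding protein gene TAGLN 0.87 (SE 0.21), and ZYX, which encodes the focal adhesion protein zyxin, 0.42 (SE 0.14). These 3 genes, with ACTA2, SRF and FHL2, were the 6 members that passed limma when adjusted over the list alone, against 0 over all genes. Cell cycle genes fell as a group, with a mean of -0.22 (SD 0.15 over 26 genes) and 25 of 26 negative (camera adjusted p = 8.34e-13, and adjusted p = 0.0218 with an estimated correlation). The mitotic kinesin gene KIF20A (-0.43, SE 0.11) was the 1 member past limma when adjusted over the list alone, against 0 over all genes. The ribonucleotide reductase gene RRM2 (-0.43, SE 0.17) and the replication gene MCM2 (-0.41, SE 0.17) did not pass. Genes of proteolysis and matrix remodelling rose, with a mean of 0.25 (SD 0.22) and 15 of 19 positive (camera adjusted p = 5.2e-09). The urokinase receptor PLAUR (0.59, SE 0.17), urokinase itself, PLAU (0.56, SE 0.19), and the matrix glycoprotein TNC (0.59, SE 0.18) were its members with the smallest p. None passed limma adjusted over the list alone or over all genes (0 in both).

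The inflammatory cytokines and NF-kB targets rose under pressure, with a mean of 0.22 (SD 0.19) and 13 of 14 positive (camera adjusted p = 1.2e-07). The neutrophil chemokine CXCL8 (0.505, SE 0.13), the adhesion receptor ICAM1 (0.36, SE 0.11) and the cytokine IL1A (0.50, SE 0.17) were the 3 that passed limma when adjusted over the list alone, against 0 over all genes. Immediate early genes, transcribed within minutes of growth factor signals, had a mean of 0.245 (SD 0.32) with 13 of 18 positive (camera adjusted p = 1.47e-06, and adjusted p = 0.142 with an estimated correlation). ERK feedback genes, which encode brakes on the MAP kinase pathway and its early targets, rose with a mean of 0.23 (SD 0.19) and 14 of 15 positive (camera adjusted p = 8.11e-06). The stress response gene IER3 (0.58, SE 0.15), a member of both lists, was in each the 1 gene past limma when adjusted over the list alone, against 0 over all genes. Genes of hypoxia and glycolysis rose with a mean of 0.18 (SD 0.17) and 11 of 14 positive (camera adjusted p = 3.72e-06). The collagen hydroxylase gene P4HA1 (0.33, SE 0.11) led this list, with 0 members past limma adjusted over the list alone or over all genes. Interferon-stimulated genes had a mean of 0.14 (SD 0.10) with 12 of 12 positive (camera adjusted p = 0.000188, and adjusted p = 0.216 with an estimated correlation). The ubiquitin-like modifier ISG15 (0.36, SE 0.15) led it, with 0 past limma adjusted over the list alone or over all genes. In all, camera called 8 of the 24 lists, and 6 of the 8 held with an estimated correlation. The rotation test fry called 1 of the 24, proteolysis and matrix remodelling (adjusted p = 0.0182). Its adjusted p was 0.0582 for cell cycle and for hypoxia and glycolysis, 0.0863 for the SRF and actin, inflammatory and ERK feedback lists, 0.326 for immediate early genes and 0.352 for interferon-stimulated genes. limma called 0 of the 7178 genes for pressure against control. An unadjusted p under 0.05 was found for 235 genes (135 higher, 100 lower), where 359 would be expected if no gene differed.

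The largest single-array differences under pressure at each time are given here as values with no test. At 1 h the highest were FOS (1.496), which encodes an early transcription factor, IL1A (0.96), UBA6 (0.93), the collagenase gene MMP13 (0.92) and FLRT2 (0.885). The lowest at 1 h were CUEDC1 (-0.74), TKFC (-0.69), CDC40 (-0.66), FMO2 (-0.65) and RGS2 (-0.62). At 3 h the highest were the stress-induced transcription factor gene ATF3 (1.88), PLAUR (1.11), BBIP1 (1.11), SRF (1.10) and the focal adhesion gene TGFB1I1 (1.03). The lowest at 3 h were SLC38A1 (-1.89), EIF5A (-1.86), EGFR (-1.73), ZNF91 (-1.67) and MEX3D (-1.62). At 8 h the highest were MYL9 (2.51), TGFB1I1 (1.99), TAGLN (1.705), the interferon-induced GTPase gene GBP1 (1.705) and the endothelin gene EDN2 (1.55). The lowest at 8 h were the replication gene MCM6 (-1.235), KCTD12 (-1.02), CCND2 (-0.97), RRM2 (-0.91) and TNS3 (-0.89). HBEGF, itself the gene of an EGFR ligand, differed by 0.75, 0.425 and 0.098 at the 3 times, with a fitted difference of 0.47 (SE 0.20; limma adjusted p = 1). The low value of EGFR at 3 h came from 1 of its 6 probe sets, and the other 5 differed by between -0.24 and 0.05. That probe set represents EGFR in every comparison here. At least 2-fold differences numbered 1 gene at 1 h, 32 at 3 h (6 higher, 26 lower) and 15 at 8 h (13 higher, 2 lower). Between unstimulated arrays of 1 batch, 3 genes differed 2-fold from 0 to 1 h and 0 genes from 3 to 8 h. The 26 lower genes of 3 h had a median difference of 0.62 between batch 2 and batch 1, fitted without the control and pressure arrays of 3 h, and their median difference under pressure at 8 h was 0.12.

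The time trend asked whether the pressure effect grows or fades, as a slope on the log2 of hours plus 1. The SRF and actin cytoskeleton genes had slopes that averaged 0.245 (SD 0.28), with 16 of 18 positive (camera adjusted p = 1.18e-08, and adjusted p = 0.269 with an estimated correlation). Their median differences were 0.18 at 1 h, 0.34 at 3 h and 0.50 at 8 h, each at percentile 100 among 10000 random lists matched for expression. The pressure arrays of 3 and 8 h, but not that of 1 h, lay further from batch 2 than their controls on the first principal component. Whether this adds to the growth with time was not tested. MYL9 had a slope of 1.05 (SE 0.17) and was the 1 member past limma when adjusted over the list alone, against 0 over all genes. The inflammatory list moved the other way, with a mean slope of -0.16 (SD 0.25) and 12 of 14 negative (camera adjusted p = 0.000431, and adjusted p = 0.269 with an estimated correlation). Its median differences were 0.26, 0.18 and 0.017 at the 3 times. The chemokine gene CXCL3 (-0.64, SE 0.15) and IL1A (-0.48, SE 0.12) passed limma when adjusted over the list alone, against 0 over all genes. Of the 8 EGFR ligands listed, 6 were on the array, and only HBEGF and TGFA were bright enough to be tested. This list had a mean slope of -0.26 (SD 0.18, camera adjusted p = 0.0442, and adjusted p = 0.408 with an estimated correlation). HBEGF (-0.39, SE 0.13) was the 1 of the 2 past limma when adjusted over the list alone, against 0 over all genes. limma called 0 genes for the time trend, with 183 at an unadjusted p under 0.05 and a smallest adjusted p of 0.21. Batch 1 held pressure and control only at 3 and 8 h. A slope within it leans on the pressure array of 3 h, with few arrays left to estimate the spread. When only batch 1 was used, limma called 39 genes (34 rising, 5 falling). It called 3 without the pressure array of 3 h and the pressure with AG1478 arrays of 3 and 8 h, and 2 without the pressure with AG1478 array of 1, 3 or 8 h. The inflammatory call was lost in camera without control at 8 h (adjusted p = 0.0874), pressure at 1 h (0.193) or pressure at 8 h (0.078). The EGFR ligand call was lost in camera without any 1 of the 4 control arrays (adjusted p = 0.0627 at 0 h, 0.0652 at 1 h, 0.0627 at 3 h and 0.0874 at 8 h), pressure at 1 h (0.327) or 8 h (0.47), AG1478 at 0 h (0.0627) or any 1 pressure with AG1478 array (0.0534).

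**Figure D2:**
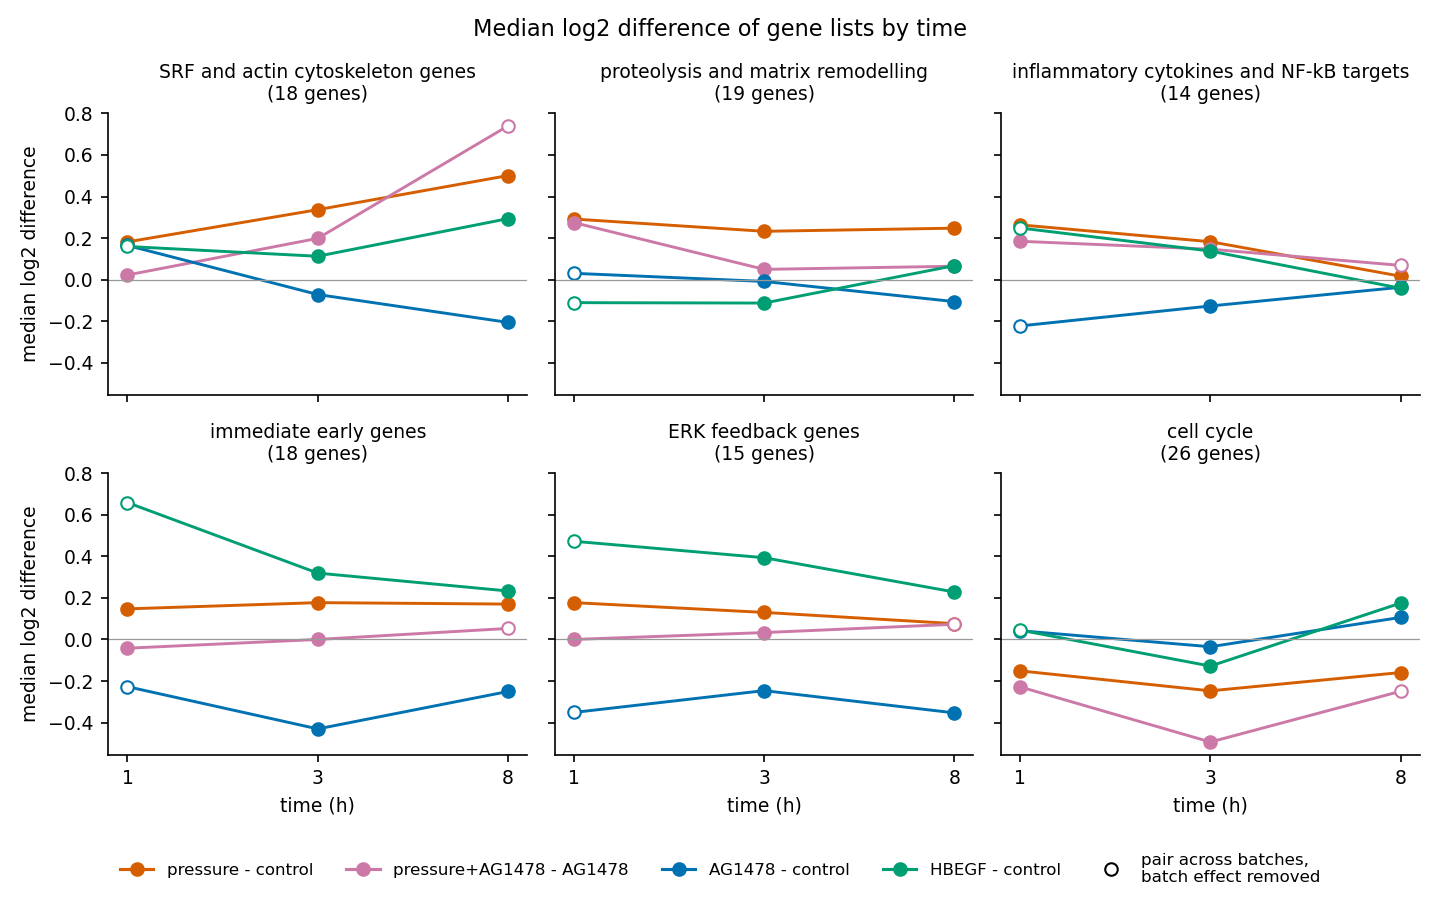
Median log2 difference of 6 gene lists at 1, 3 and 8 h for 4 pairs of conditions, where lines join the times and open circles mark pairs of arrays from different batches with the fitted batch effect removed. The SRF and actin cytoskeleton median under pressure goes from 0.18 to 0.50, and the immediate early median is 0.66, 0.32 and 0.23 after HBEGF and below 0 at every time under AG1478.

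Pressure with AG1478 against AG1478 asked which responses to pressure occur with the EGFR kinase inhibited. The SRF and actin cytoskeleton genes had a mean fitted difference of 0.36 (SD 0.34) with 17 of 18 positive (camera adjusted p = 3.88e-08, and adjusted p = 0.168 with an estimated correlation). TAGLN, at 1.11 (SE 0.22), was the 1 member past limma when adjusted over the list alone, against 0 over all genes. MYL9 was at 1.05 (SE 0.36). The median difference of the list was 0.023 at 1 h, with 9 members up and 9 down, and 0.20 at 3 h. At 8 h, across batches, it was 0.31 as deposited (11 up, 7 down). With the batch effect removed it was 0.74 (17 up, 1 down). Proteolysis and matrix remodelling genes rose, with a mean of 0.28 (SD 0.30) and 16 of 19 positive (camera adjusted p = 7.54e-07). This was the 1 call that held in camera with an estimated correlation (adjusted p = 0.00886). PLAUR (0.91, SE 0.185) and PLAU (0.90, SE 0.21) passed limma when adjusted over the list alone, against 0 over all genes. Cell cycle genes had a mean of -0.30 (SD 0.19) with 24 of 26 negative (camera adjusted p = 3.71e-06, and adjusted p = 0.168 with an estimated correlation). The topoisomerase gene TOP2A (-0.62, SE 0.145), the cyclin gene CCNB1 (-0.58, SE 0.16), NUSAP1 (-0.50, SE 0.13) and KIF20A (-0.49, SE 0.12) were among the 7 past limma when adjusted over the list alone, against 0 over all genes. The inflammatory list had a mean of 0.21 (SD 0.215) with 11 of 14 positive (camera adjusted p = 5.19e-05, and adjusted p = 0.168 with an estimated correlation). ICAM1 (0.525, SE 0.12) and the chemokine gene CCL20 (0.605, SE 0.19) passed limma when adjusted over the list alone, against 0 over all genes. The fibroblast markers had a mean of 0.27 (SD 0.25) with 5 of 5 positive (camera adjusted p = 0.00142, and adjusted p = 0.215 with an estimated correlation). The vimentin gene VIM (0.72, SE 0.16), also expressed by migrating epithelial cells, was the 1 past limma when adjusted over the list alone, against 0 over all genes. The collagen genes COL1A1 and COL1A2 were at 0.14 (SE 0.12) and 0.21 (SE 0.12).

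limma called 0 genes for pressure under AG1478, where 1111 genes had an unadjusted p under 0.05 (272 higher, 839 lower; 359 expected), and the smallest adjusted p was 0.136. It called 99 genes without the pressure with AG1478 array of 1 h, and 1 without pressure at 3 h or without pressure with AG1478 at 8 h. The fibroblast call was lost in camera without the pressure with AG1478 array of 1 h (adjusted p = 0.093). At 1 h the highest single-array differences were in MMP7 (1.404), FN1 (1.16), TAGLN (1.12), MMP10 (0.96) and GPNMB (0.86). The lowest were in SPRR3 (-1.05), EGFR (-0.88), UGCG (-0.87), GOSR1 (-0.79) and KMT5B (-0.66). At 3 h the highest were in ATF3 (2.23), PYY2 (1.73), ZER1 (1.56), PLAU (1.41) and SCARB2 (1.26). The lowest were in the phosphatase gene DUSP4 (-1.76), INSR (-1.75), FOXO3 (-1.68), RCOR1 (-1.65) and PLEKHA5 (-1.57). These 3 h values include the array with the narrowest spread, in which the median gene differed by -0.16. The 3′ minus 5′ signal of the pair was -0.18 for ACTB and -0.052 for GAPDH under pressure with AG1478, against 0.70 and 0.29 under AG1478. Against that shift the cell cycle median was -0.49 (-0.15 in random lists matched for expression) and the SRF and actin median was 0.20 (-0.17 in random lists). At 8 h the pair crosses batches, and as deposited the extremes were SLC16A7 (3.07), NR1D2 (2.98), ZBTB38 (2.765), GLIPR1 (2.60) and MBP (2.43) at the high end. At the low end were YWHAE (-2.22), EPHX1 (-1.84), PPDPF (-1.81), FASN (-1.74) and SH3GLB2 (-1.72). With the batch effect removed, an order chosen after its values were seen, the highest at 8 h were MYL9 (2.01), the tropomyosin gene TPM4 (1.98), TGFB1I1 (1.96), SCARB2 (1.90) and the actin-bundling gene FSCN1 (1.88). The lowest were FOXO3 (-1.245), RIPK4 (-1.19), PRKCI (-1.13), CXCL14 (-1.12) and TNS3 (-1.09). In the same order, the as-deposited values were 0.94, 0.30, 1.14, 1.73 and 0.75 for the highest. For the lowest they were -0.58, -0.80, 1.365, -1.22 and -0.41, so PRKCI changed sign. The size of these differences thus depends on the subtracted batch effect. At least 2-fold differences numbered 4 genes at 1 h, 129 at 3 h (16 higher, 113 lower) and 283 at 8 h, or 49 at 8 h with the batch effect removed. HBEGF differed by -0.16, -0.24 and 0.38 at the 3 times, and with the batch effect removed its difference at 8 h was -0.35. Its fitted difference was -0.29 (SE 0.22; limma adjusted p = 0.522). EGFR had a fitted difference of -1.07 (SE 0.44; limma adjusted p = 0.277), with an 8 h difference of 1.37 as deposited and -1.02 with the batch effect removed. These EGFR values rest on the probe set that stood apart from its others at 3 h of pressure.

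The change of the pressure effect by AG1478 is the difference between those 2 effects, the question behind the series title. ERK feedback genes had a mean difference of -0.30 (SD 0.35) with 13 of 15 negative (camera adjusted p = 0.192): the ERK phosphatase gene DUSP6 was at -0.79 (SE 0.27), DUSP4 at -1.03 (SE 0.50) and MAFF at -0.86 (SE 0.345). HBEGF was at -0.76 (SE 0.29; limma adjusted p = 0.963 over all genes) and passed limma when adjusted over the list alone. The list of the 2 EGFR ligands tested had a mean of -0.44 (SD 0.455, camera adjusted p = 0.358). Fibroblast markers had a mean of 0.18 (SD 0.13) with 5 of 5 positive (camera adjusted p = 0.0878), and interferon-stimulated genes -0.17 (SD 0.14) with 10 of 12 negative (camera adjusted p = 0.192). The SRF and actin genes had a mean difference of -0.019 (SD 0.19) and a median of -0.011 with a test direction above 0 (camera adjusted p = 0.614). As deposited, their median changes were -0.084 at 1 h, -0.154 at 3 h and -0.643 at 8 h, where 1 of the pairs crosses batches. camera called 0 of the 24 lists with either correlation, and limma called 0 genes, with 270 at an unadjusted p under 0.05. A value short of the threshold does not show that pressure acted alike with and without AG1478. camera called 4 lists (1 up, 3 down) without the pressure array of 3 h and the pressure with AG1478 arrays of 3 and 8 h. It called 2 without pressure or HBEGF at 1 h, without a batch term or in batch 1 alone, and 1 without control at 1 h, AG1478 at 3 h, AG1478 at 8 h, pressure with AG1478 at 8 h or all arrays of 1 h.

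Over the 15 genes that differed 2-fold under pressure at 8 h, the share of the pressure difference kept under AG1478 at 3 h was 0.861 (95% bootstrap interval over genes 0.389 to 1.17), and 11 of the 15 had the same sign in both. ATF3 differed by 1.88 without and 2.23 with AG1478 at 3 h, EDN2 by 0.87 and 0.88, GBP1 by 0.73 and 1.21, TAGLN by 0.50 and 0.55, MYL9 by 0.97 and 0.42, and TGFB1I1 by 1.03 and -0.17. These genes are not independent replicates. ATF3 had the largest differences of the genes named here and so weighs most among them in the slope. On the first principal component, which separates the batches, both 3 h pressure arrays lay above their partners. Their scores were 12.2 against 6.18 without AG1478 and 23.9 against 9.03 with it. Whether a shift shared by these arrays adds to the share was not tested. With 104 genes picked at 1.5-fold the share was 0.669 (0.422 to 0.896), with 65 of the same sign. With 32 genes picked at 3 h and measured at 8 h, across batches, it was 1.05 (0.739 to 1.73), with 28 of the same sign. With the batch effect removed this was 0.751 (0.048 to 0.971), with 16 of 32 of the same sign. Under pressure alone, only 11 of these 32 genes had the same sign at 8 h as at 3 h, against 12 of the 15. Most of the 32 thus no longer showed the response they were picked for. Picked at 1 h, a single gene passed and gave a share of -0.052.

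AG1478 against control asked what the inhibitor does without pressure. CXCL8 fell, with a fitted difference of -0.876 (SE 0.13; limma adjusted p = 0.0259) and single-array differences of -1.31, -0.82 and -1.18 at 1, 3 and 8 h (-0.98 at 1 h with the batch effect removed). CYP1B1, the gene of a cytochrome P450 induced by the aryl hydrocarbon receptor, rose by 1.58 (SE 0.22; limma adjusted p = 0.0249), with differences of -0.46 at 1 h, where the pair crosses batches (1.28 with the batch effect removed), and 1.345 and 2.44 at 3 and 8 h. CYP1B1 was chosen to be followed in more detail after its values were seen. Its other probe sets were higher by 0.11 to 1.61 at 3 h and by 0.15 to 1.57 at 8 h, so the size depends on the probe set. Lower at least 2-fold at all 3 times, as values only, were HS3ST1 (-2.11, -1.03 and -1.05 at 1, 3 and 8 h), FOS (-1.05, -1.54 and -1.25), the kinase gene STK17A (-1.35, -1.24 and -1.08) and the ERK phosphatase gene DUSP5 (-1.06, -1.31 and -1.11). Their 1 h values cross batches, and with the batch effect removed they were -1.24 for HS3ST1, -1.02 for FOS, -0.945 for STK17A and -1.26 for DUSP5. The batch effect was fitted with a constant effect of AG1478 assumed. The 1 h values without it, also those of CXCL8 and CYP1B1, are thus not independent of the fitted differences. Immediate early genes had a mean of -0.36 (SD 0.375) with 14 of 18 negative (camera adjusted p = 1.13e-11, and adjusted p = 0.107 with an estimated correlation). The early transcription factor genes FOS (-1.17, SE 0.33), EGR1 (-0.94, SE 0.23) and MYC (-0.76, SE 0.16) were among the 8 past limma when adjusted over the list alone, against 0 over all genes. ERK feedback genes had a mean of -0.31 (SD 0.38) with 10 of 15 negative (camera adjusted p = 1.41e-05, and adjusted p = 0.0592 with an estimated correlation). DUSP5 (-1.07, SE 0.32), IER3 (-0.74, SE 0.15) and CCND1 (-0.67, SE 0.21) were among 5 past limma when adjusted over the list alone, against 0 over all genes. DUSP6, of the same list, differed by -0.63 at both 3 and 8 h on the probe set used here. Its other probe sets differed by -2.76 and -1.08 at 3 h and by -2.56 and -1.45 at 8 h, so its size depends on the probe set. The inflammatory list had a mean of -0.23 (SD 0.34) with 10 of 14 negative (camera adjusted p = 4.57e-05, and adjusted p = 0.108 with an estimated correlation). CXCL8, IL1A (-0.74, SE 0.17), CCL20, CXCL1 and CXCL3 were the 5 past limma when adjusted over the list alone, against 1 over all genes. The 3′ minus 5′ signal moved with the inhibitor in the pairs within batch 1: for ACTB it was 0.70 at 3 h and 0.24 at 8 h under AG1478, against -0.21 and -0.12 in control, and for GAPDH 0.29 and 0.43 against -0.032 and -0.039.

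Another 5 lists passed camera under AG1478. EGFR ligands had a mean of -0.40 (SD 0.36; camera adjusted p = 0.0161, and adjusted p = 0.108 with an estimated correlation). HBEGF (-0.65, SE 0.20) passed limma when adjusted over the list alone but not over all genes (adjusted p = 0.977). YAP/TAZ targets, genes of the Hippo pathway's coactivators, had a mean of -0.14 (SD 0.27) with 8 of 12 negative (camera adjusted p = 0.0313, and adjusted p = 0.108 with an estimated correlation). CCN2 (-0.745, SE 0.19) was the 1 past limma when adjusted over the list alone, against 0 over all genes. Cholesterol biosynthesis genes had a mean of -0.10 (SD 0.18) with 11 of 17 negative (camera adjusted p = 0.0161, and adjusted p = 0.559 with an estimated correlation). INSIG1 (-0.36, SE 0.13), which encodes a brake on sterol synthesis, led it, with 0 past limma adjusted over the list alone or over all genes. The aryl hydrocarbon receptor targets had a mean of 0.49 (SD 0.75) with 3 of 4 positive (camera adjusted p = 0.00574, and adjusted p = 0.108 with an estimated correlation). CYP1B1 and the aldehyde dehydrogenase gene ALDH3A1 (0.36, SE 0.14) passed limma when adjusted over the list alone, against 1 over all genes. FOXO targets, which growth factor signalling represses, had a mean of 0.16 (SD 0.30) with 10 of 12 positive (camera adjusted p = 0.0131, and adjusted p = 0.253 with an estimated correlation). TXNIP (0.55, SE 0.12), ERBB3 (0.36, SE 0.11) and PIK3IP1 (0.41, SE 0.12) were the 3 higher and TRIB2 (-0.415, SE 0.11) the 1 lower past limma when adjusted over the list alone, against 0 over all genes. camera called 8 lists under AG1478, 0 of them held with an estimated correlation, and fry called 0. limma called 2 genes, with 291 at an unadjusted p under 0.05. It called 0 without control at 1, 3 or 8 h, AG1478 at 3 h, or pressure with AG1478 at 1 or 8 h, 1 without AG1478 at 1 or 8 h, and 5 without control or AG1478 at 0 h. In a fit of only the AG1478 and control arrays it called 48 (5 higher, 43 lower). The ligand, YAP/TAZ, aryl hydrocarbon receptor and FOXO calls were each lost without control at 0 h or AG1478 at 0 h (camera adjusted p = 0.0982 each). They were also lost in camera, with that of cholesterol biosynthesis (adjusted p = 0.0809), without pressure with AG1478 at 8 h (0.051 for the ligands and the aryl hydrocarbon receptor targets, 0.115 for YAP/TAZ and 0.134 for FOXO). The ligand and YAP/TAZ calls were also lost in camera without control at 3 h (adjusted p = 0.0506 and 0.0622). Further camera losses were those of YAP/TAZ and FOXO without AG1478 at 3 h (adjusted p = 0.215 and 0.173), that of YAP/TAZ without pressure at 8 h (0.0616), and that of cholesterol biosynthesis without AG1478 at 8 h (0.667). At least 2-fold differences numbered 219 genes at 0 h and 419 at 1 h across batches, or 25 and 5 with the batch effect removed. They numbered 15 at 3 h (1 higher, 14 lower) and 36 at 8 h (2 higher, 34 lower) within batch 1. EGFR had a fitted difference of 0.19 (SE 0.41; limma adjusted p = 0.984).

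**Figure D3:**
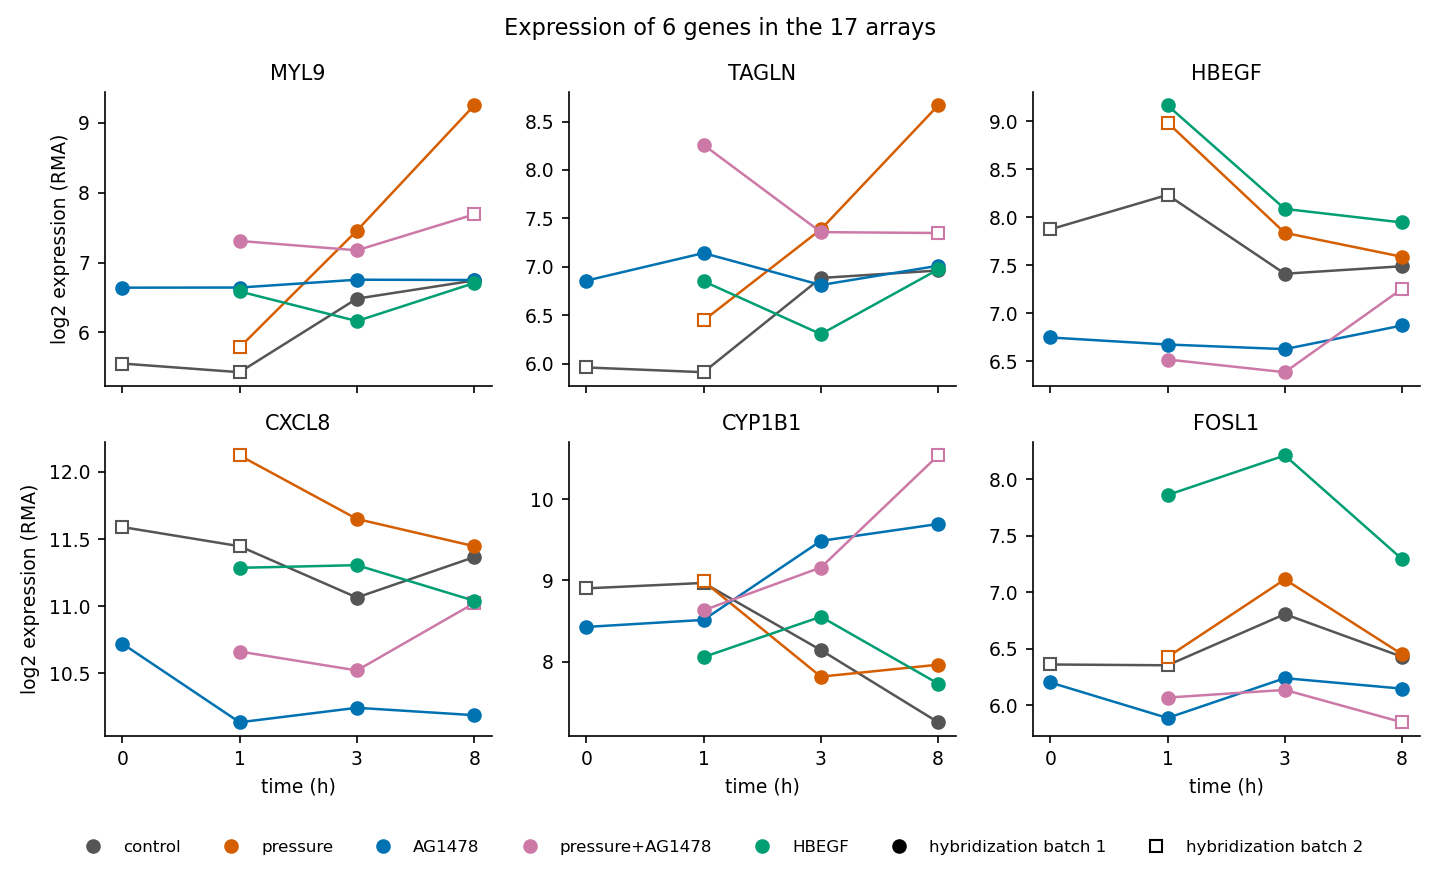
Log2 expression of MYL9, TAGLN, HBEGF, CXCL8, CYP1B1 and FOSL1 in each of the 17 arrays against time, with 1 line per stimulus, filled circles for hybridization batch 1 and open squares for batch 2. MYL9 is at 9.25 under pressure at 8 h against 6.74 in control, and CYP1B1 is at 9.70 under AG1478 at 8 h against 7.25 in control.

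HBEGF against control asked what the EGFR ligand does on its own. FOSL1, the gene of an AP-1 transcription factor induced by ERK, rose by 1.23 (SE 0.15; limma adjusted p = 0.00616), with single-array differences of 1.51, 1.41 and 0.865 at 1, 3 and 8 h. DUSP6, the gene of a phosphatase that turns ERK off, rose by 1.38 (SE 0.20; limma adjusted p = 0.0184), with differences of 1.79, 1.02 and 0.998. GAS1, a gene linked to growth arrest, fell by 0.83 on the log2 scale (SE 0.13; limma adjusted p = 0.037), with differences of -1.15, -1.08 and -0.63. The 1 h values of these 3 genes cross batches, and with the batch effect removed they were 1.35 for FOSL1, 2.07 for DUSP6 and -0.634 for GAS1. The batch effect was fitted with a constant effect of HBEGF assumed, so these values are not independent of the fitted differences. Immediate early genes had a mean of 0.47 (SD 0.40) with 17 of 18 positive (camera adjusted p = 6.27e-11, and adjusted p = 0.126 with an estimated correlation). FOSL1, MYC (0.83, SE 0.17), IER3 (0.73, SE 0.16) and EGR1 (1.02, SE 0.24) were among the 10 past limma when adjusted over the list alone, against 1 over all genes. ERK feedback genes rose with a mean of 0.45 (SD 0.41) and 14 of 15 positive (camera adjusted p = 6.8e-07). DUSP6 and IER3 were the 2 past limma when adjusted over the list alone, against 1 over all genes. HBEGF itself was at 0.97 (SE 0.22; limma adjusted p = 0.213) and EGFR at 0.54 (SE 0.44; limma adjusted p = 0.76). camera called 2 of the 24 lists, and ERK feedback held with an estimated correlation (adjusted p = 0.0304). limma called 3 genes, with 633 at an unadjusted p under 0.05, and 65 (23 higher, 42 lower) in a fit of only the HBEGF and control arrays. The 3′ minus 5′ signal of ACTB was -0.39 after HBEGF against 0.96 in control at 1 h, -0.30 against -0.21 at 3 h and -0.26 against -0.12 at 8 h.

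As values, the highest single-array differences after HBEGF at 3 h were FOSL1, the lipid enzyme gene UGCG (1.10), the phosphate transporter gene SLC20A1 (1.08), DUSP6 and the plasminogen activator gene PLAT (1.01). The lowest at 3 h were HACD2 (-1.16), MMP10 (-1.14), SLC19A2 (-1.10), GAS1 and TMEM123 (-1.07). At 8 h the highest were TRIB3 (1.07), the serine synthesis gene PSAT1 (1.04), DUSP6, UPP1 (0.96) and PRSS3 (0.94). The lowest at 8 h were TSPAN12 (-1.15), EGFL6 (-1.09), FNBP1L (-0.98), NCOA2 (-0.96) and ADH7 (-0.96). At 1 h the pair crosses batches, and as deposited the extremes were YWHAE (3.53), PPDPF (3.08), TMEM259 (2.645), FOS (2.60) and SH3GLB2 (2.58) at the high end. At the low end were SLC16A7 (-3.91), ZBTB38 (-3.485), RYBP (-3.36), DYNC1LI2 (-3.325) and TNPO1 (-3.21). With the batch effect removed, an order chosen after its values were seen, the highest were FOS (2.635), DUSP6 (2.07), EGR1 (1.99), HBEGF (1.66) and DUSP5 (1.601). The lowest were CXCL6 (-1.13), MEX3D (-1.10), CDS1 (-1.10), MAGT1 (-1.10) and EBAG9 (-1.065). At least 2-fold differences numbered 559 genes at 1 h, or 19 with the batch effect removed, 13 at 3 h (5 higher, 8 lower) and 4 at 8 h (2 higher, 2 lower). limma called 0 genes without control at 3 h, control at 8 h or HBEGF at 3 h, 1 without control at 1 h or pressure with AG1478 at 8 h, and 5 without pressure with AG1478 at 3 h or HBEGF at 1 h. With only batch 1, or with the dimmest 60% of genes left out, it called 0 genes. GAS1 was at -0.51 with all of its probe sets averaged, below the threshold.

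HBEGF against pressure compared the ligand with the mechanical stimulus directly. FOSL1 (1.07, SE 0.15; limma adjusted p = 0.0162), MYC (0.96, SE 0.17; limma adjusted p = 0.0465) and the follistatin gene FST (0.905, SE 0.15; limma adjusted p = 0.028) were higher after HBEGF. The stromelysin gene MMP10 (-1.33, SE 0.20; limma adjusted p = 0.0215), the integrin gene ITGAV (-0.86, SE 0.12; limma adjusted p = 0.0162), the interferon-induced gene IFIT1 (-0.78, SE 0.125; limma adjusted p = 0.028), BPGM (-0.87, SE 0.15; limma adjusted p = 0.0315) and the kinase gene STK38L (-0.67, SE 0.11; limma adjusted p = 0.0315) were lower. All 8 had the same sign at 1, 3 and 8 h as deposited, where the 1 h pair crosses batches. Cell cycle genes were higher after HBEGF than under pressure, with a mean of 0.23 (SD 0.14) and 26 of 26 positive (camera adjusted p = 3.18e-06, and adjusted p = 0.215 with an estimated correlation). The spindle gene TPX2 (0.315, SE 0.10) led them, with 0 past limma adjusted over the list alone or over all genes. Proteolysis and matrix remodelling genes were lower, with a mean of -0.305 (SD 0.45) and 13 of 19 negative (camera adjusted p = 8.21e-05, and adjusted p = 0.0328 with an estimated correlation). ITGAV, MMP10, MMP9, PLAUR, MMP13, TNC and FN1 were the 7 past limma when adjusted over the list alone, against 2 over all genes. Interferon-stimulated genes had a mean of -0.26 (SD 0.24) with 11 of 12 negative (camera adjusted p = 1.55e-05, and adjusted p = 0.233 with an estimated correlation). IFIT1, IFI44, MX2, IFIT3 and ISG15 were the 5 past limma adjusted over the list alone, against 1 over all genes. Immediate early genes had a mean of 0.23 (SD 0.53) with 13 of 18 positive (camera adjusted p = 0.00434, and adjusted p = 0.415 with an estimated correlation). FOSL1, MYC, EGR1 (1.06, SE 0.24) and JUNB were the 4 past limma adjusted over the list alone, against 2 over all genes. The SRF and actin list had a mean of -0.24 (SD 0.42) with 11 of 18 negative (camera adjusted p = 0.00892, and adjusted p = 0.415 with an estimated correlation). TAGLN (-1.19, SE 0.22) and MYL9 (-1.37, SE 0.36) passed limma when adjusted over the list alone, against 0 over all genes. Hypoxia and glycolysis genes had a mean of -0.17 (SD 0.29) with 9 of 14 negative (camera adjusted p = 0.00962, and adjusted p = 0.215 with an estimated correlation). BNIP3 (-0.69, SE 0.15), KDM3A, SLC2A1 and P4HA1 were the 4 past limma adjusted over the list alone, against 0 over all genes.

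limma called 8 genes for HBEGF against pressure, with 684 at an unadjusted p under 0.05 (300 higher, 384 lower), and 19 (6 higher, 13 lower) in a fit of only the stimuli compared. It called 0 without pressure at 1 h, pressure at 8 h or HBEGF at 3 h, 1 without HBEGF at 8 h, 2 without pressure at 3 h and 3 without control at 1 or 3 h. It called 5 without control at 8 h or pressure with AG1478 at 1 h, 16 without pressure with AG1478 at 8 h, 17 without pressure with AG1478 at 3 h or HBEGF at 1 h, and 0 with only batch 1. The immediate early call was lost in camera without HBEGF at 1 h (adjusted p = 0.319) and the SRF and actin call without pressure at 8 h (adjusted p = 0.439). Across genes, the correlation of the pressure difference at 8 h with the HBEGF difference at 3 h was 0.236 and that of pressure at 3 h with HBEGF at 8 h was -0.061, with a mean of 0.088. At matched times, where both differences share the control array, the correlations were 0.127 at 3 h and 0.453 at 8 h (mean 0.29), and simulated arrays with no effect gave 0.50 through the shared control. The covariance at matched times was 0.0071 at 3 h and 0.0226 at 8 h, against 0.0294 in the simulated arrays with no effect and 0.0146 from the difference between the control arrays of 3 and 8 h, a measure chosen after the result was seen. It was below both at 3 h, and below the first and above the second at 8 h. Genes are not independent replicates in these correlations.

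Markers of other cell types and other lists gave no call in camera for pressure against control. Secretory cell markers had a mean of 0.063 (SD 0.098 over 16 genes; camera adjusted p = 0.141), basal cell markers 0 (SD 0.20 over 12 genes; adjusted p = 0.963, median -0.016) and ciliated cell markers -0.058 (SD 0.11 over 4 genes; adjusted p = 0.525). The basal mean hides medians of 0.217 at 1 h (percentile 99.99 among random lists, 10 of 12 higher), -0.042 at 3 h and -0.156 at 8 h (percentile 0.55, 9 of 12 lower). Their mean slope over time was -0.08 (SD 0.16; camera adjusted p = 0.0901). The squamous differentiation list was at 0.01 (SD 0.18 over 16 genes; camera adjusted p = 0.709), where the stress keratin gene KRT16 was at 0.475 (SE 0.23). Fibroblast markers were at 0.092 (SD 0.15 over 5 genes; camera adjusted p = 0.187), and endothelial and leukocyte markers at 0.056 (SD 0.25 over 4 genes; adjusted p = 0.55). CD14 (0.37, SE 0.11), a monocyte receptor gene, was the 1 past limma when adjusted over the list alone, against 0 over all genes. YAP/TAZ targets were at -0.077 (SD 0.071 over 12 genes; camera adjusted p = 0.141) and TGF-beta and BMP targets at 0.051 (SD 0.215 over 9 genes; adjusted p = 0.237). The unfolded protein and integrated stress response list was at 0.084 (SD 0.23 over 14 genes; camera adjusted p = 0.146), with ATF4 at 0.42 (SE 0.15) and the chaperone gene HSPA5 at -0.28 (SE 0.16). Heat shock genes were at -0.011 (SD 0.14 over 10 genes; camera adjusted p = 0.709), NRF2 targets at 0.068 (SD 0.12 over 10 genes; adjusted p = 0.171), and EGFR family receptors and sheddases at -0.045 (SD 0.097 over 7 genes; adjusted p = 0.709). EGFR ligands were at 0.185 (SD 0.40 over 2 genes; camera adjusted p = 0.393), aryl hydrocarbon receptor targets at 0.051 (SD 0.15 over 4 genes; adjusted p = 0.497) and FOXO targets at -0.011 (SD 0.16 over 12 genes; adjusted p = 0.963). The FOXO list had a median of 0.035 and a test direction above 0. Cholesterol biosynthesis genes were at -0.008 (SD 0.10 over 17 genes; camera adjusted p = 0.963), with a median of -0.005 and a test direction above 0. In the 7 comparisons the test, the median and the mean of a list did not all share a sign for 2, 8, 7, 3, 3, 2 and 3 of the 24 lists, in the order pressure, pressure under AG1478, their difference, AG1478, HBEGF, HBEGF against pressure and time trend, and 0 of these lists were called.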

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

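The values with the batch effect removed were chosen after the results of this part were seen, and the other comparisons before. 3 lists stood out because their response to pressure depended on time in a camera test of slopes: the EGFR ligands (mean slope -0.259), the inflammatory cytokines and NF-kB targets (-0.161) and the SRF and actin cytoskeleton genes (0.245). The ligands and the inflammatory genes were highest at 1 h and the contractile genes at 8 h. An early and a late phase of the response could give these slopes, but camera with an estimated correlation called 0 lists for the time trend, and 17 of the 35 splits of the arrays called at least as many lists as the real 3.

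Another 2 lists stood out because their median difference under pressure had 1 sign without AG1478 and the other sign with it at 1, 3 and 8 h. The mean distance between the medians was 0.143 for YAP/TAZ targets, lower under pressure alone, and -0.143 for secretory cell markers, higher under pressure alone. The opposite signs at single times were not tested. The fitted change of the pressure effect by AG1478 was tested in camera and was not called for either list (adjusted p = 0.192 for YAP/TAZ targets and 0.89 for secretory markers). The secretory medians under AG1478 of -0.016 at 1 h and -0.144 at 3 h were near those of random lists matched for expression (-0.015 and -0.137). The 8 h pair with AG1478 crosses batches. With the batch effect removed its medians were -0.06 for YAP/TAZ targets and 0.12 for secretory markers. The opposite signs at that time therefore depend on whether the batch effect is removed. That effect was fitted with the same array among others and can absorb a response particular to that time, so neither set of values decides.

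Of the 198 named genes, 8 had opposite signs with and without AG1478 at every time, where 6.2 would be expected if the 6 signs were random. The named genes were picked in part for their differences on these same arrays. Random signs are therefore no fair reference, and the count decides nothing. All 8 were higher under pressure alone and lower under pressure with AG1478. The opposite signs at single times were not tested, and limma called none of the 8 for the fitted change of the pressure effect by AG1478 (smallest adjusted p = 0.963). The median gene under pressure with AG1478 at 3 h was at -0.155, which favours this direction, and MVD (-0.087), SPDEF (-0.051), S100A9 (-0.104) and IFIT3 (-0.092) lay above that shift. The mean distances were -0.372 for the sterol synthesis gene MVD, -0.44 for the goblet cell regulator SPDEF, -0.447 for the trefoil factor gene TFF3, -0.501 for the mucin gene MUC16, -0.329 for the calprotectin gene S100A9, -0.345 for the interferon-induced gene IFIT3, -0.719 for the cyclin gene CCND1 and -0.806 for the actin crosslinker gene ACTN4. These distances rest in part on the 8 h pair that crosses batches. With the batch effect removed the 8 h difference under AG1478 turned to 0.385 in MVD, 0.246 in SPDEF and 0.284 in CCND1, so 5 of the 8 stayed opposite, and that of ACTN4 went from -1.21 to -0.26. As deposited, CCND1 went 0.572, 0.287 and 0.065 without AG1478 and -0.086, -0.578 and -0.568 with it.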

How the results depend on the processing

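The alternatives of this part were set before the results, except the fits without the pressure array of 3 h and the pressure with AG1478 arrays of 3 and 8 h (called the 3 doubted arrays here) and, for the lists, all counts with 1 array left out and all counts without the 1 h, 3 h or 8 h arrays. These were chosen after the results were seen. Of the 722 values for named genes, 654 kept the same call in every setting. A change of direction was counted only for a gene called in the main fit or in that setting. The 654 therefore include uncalled genes whose sign was free to change. The cause of the differences below was not tested. Genes called by limma changed as follows. With no hybridization batch term: 0 for AG1478 against control, 1 for HBEGF against control and 2 for HBEGF against pressure. With only hybridization batch 1: 4 for AG1478, 0 for HBEGF, 0 for HBEGF against pressure and 39 for the time trend. With the lowest 60% of genes left out: 0 for HBEGF and 4 for HBEGF against pressure. With the mean of all probe sets: 4 for AG1478. Without the 0 h arrays: 5 for AG1478. With only the stimuli compared: 48 for AG1478, 65 for HBEGF and 19 for HBEGF against pressure. Without the 1 h arrays: 0 for AG1478, 1 for HBEGF and 3 for HBEGF against pressure. Without the 3 h arrays: 0 for each of these 3. Without the 8 h arrays: 1 for pressure under AG1478 and 0 for each of these 3. Without the 3 doubted arrays: 0 for AG1478, 0 for HBEGF, 1 for HBEGF against pressure and 3 for the time trend.

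Lists called by camera changed as follows. With an estimated correlation: 1 for pressure under AG1478, 0 for AG1478, 1 for HBEGF, 1 for HBEGF against pressure and 0 for the time trend. With fry: 1 for pressure, 2 for pressure under AG1478, 0 for AG1478, 1 for HBEGF, 1 for HBEGF against pressure and 0 for the time trend. With no batch term: 8 for pressure under AG1478, 2 for the change of the pressure effect by AG1478 and 3 for AG1478. With only batch 1: 2 for the change by AG1478 and 3 for AG1478. Without the 1 h arrays: 1 for the change by AG1478 and 5 for HBEGF. Without the 3 h arrays: 4 for HBEGF and 14 for HBEGF against pressure. Without the 3 doubted arrays: 4 for the change by AG1478.

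Counts of genes at least 2-fold different moved as follows. At least 1.5-fold: 30, 191 and 104 for pressure at 1, 3 and 8 h, 25, 920 and 1143 for pressure under AG1478, 1175, 1580, 140 and 311 for AG1478 at 0, 1, 3 and 8 h, and 1873, 154 and 146 for HBEGF at 1, 3 and 8 h. With the mean of all probe sets at 3 h: 19 for pressure, 80 for pressure under AG1478 and 9 for AG1478. With the lowest 60% left out: 7 for pressure at 8 h, 2 and 71 for pressure under AG1478 at 1 and 3 h, and 2 for HBEGF at 8 h. With the batch effect removed: 49 for pressure under AG1478 at 8 h, 25 and 5 for AG1478 at 0 and 1 h, and 19 for HBEGF at 1 h. In EGFR: time trend of the pressure effect with only hybridization batch 1, the slope was reversed at 1.799, against -0.054 with all arrays. Batch 1 held pressure and control only at 3 and 8 h, so this slope leaves out their 1 h arrays. The share of the pressure response kept was reversed at -0.052 for the 1 gene picked at 1 h. The correlation of the pressure and HBEGF differences was 0.2901 at matched times, against 0.088 at unmatched times.

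With 1 array left out at a time, limma called 0 to 0 genes for pressure, 0 to 99 for pressure under AG1478, 0 to 0 for the change by AG1478, 0 to 5 for AG1478, 0 to 5 for HBEGF, 0 to 17 for HBEGF against pressure and 0 to 2 for the time trend. In the same order, and chosen later, camera called 8 to 9, 5 to 7, 0 to 2, 4 to 11, 2 to 5, 6 to 9 and 1 to 4 lists. The time trend without the 1 h, the 3 h or the 8 h arrays was not run, because too few arrays were left to estimate an error.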

Other observations

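The tests on the 26 genes lower at 3 h of pressure, on the separation of the batches, and of batch as a source of the CYP1B1 rise were written after the result was seen, and the others before. After HBEGF, single members of lists that camera did not call passed limma when adjusted over their list alone, and none of them over all genes. CDKN1B, the gene of a cell cycle inhibitor and a FOXO target, was at -0.68 (SE 0.14), and ADAM9, a sheddase gene, at -0.54 (SE 0.11). DNAJB9, a chaperone gene of the unfolded protein response, was at -0.59 (SE 0.14), and TRIB3, a gene of the same list induced by ATF4, at 0.53 (SE 0.16). SPRR1A, a gene of the cornified envelope, was at 0.49 (SE 0.12). In proteolysis and matrix remodelling 1 member was higher, TIMP1 (0.315, SE 0.10), and 3 were lower, MMP10 (-0.93, SE 0.20), ITGAV (-0.56, SE 0.12) and FN1 (-0.76, SE 0.24). The interferon-induced genes IFIT1 (-0.55, SE 0.125), IFI44 (-0.38, SE 0.12) and MX2 (-0.39, SE 0.13) were lower. VEGFA (0.51, SE 0.12) and BNIP3 (-0.47, SE 0.145) of the hypoxia and glycolysis list went opposite ways. IL1A (0.70, SE 0.18) was the 1 member of the inflammatory list, and HBEGF (0.97, SE 0.22) that of the EGFR ligands. Between AG1478 at 0 h and 1 h, 18 genes were at least 2-fold lower on single arrays, with no test.

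Splits of the arrays were refitted as a check on the numbers of calls. Where the real count was 0, every split reaches it by definition, so the share of splits that reach it carries no information. For pressure against control 0 genes were called, and all 35 splits called at least as many, with a highest other count of 0. For lists, 7 of the 35 splits reached the 8 of pressure, with a highest other count of 10. The 6 others that reached it had 1 or 2 arrays out of place, and splits with more called at most 5. A difference that partly lies along the pressure arrays is still present in such splits, so the count of 7 does not separate chance from pressure.

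For pressure under AG1478, all 35 splits reached the real 0 genes. The highest other split called 95 genes, far above the real count, which points to a structure of the samples. It set AG1478 at 3 and 8 h and pressure with AG1478 at 8 h against the rest. Those 3 arrays had ACTB 3′ minus 5′ signals of 0.70, 0.24 and 0.21, against -0.28 to -0.15 in the rest. For GAPDH the signals were 0.29, 0.43 and 0.19, against at most 0.093. Whether this signal gave the 95 calls was not tested. For lists, 7 of 35 reached the real 5, with a highest of 8. For the change of the pressure effect by AG1478, all 100 splits reached the real 0 for genes and for lists, with highest counts of 34 genes and 9 lists, which also points to a structure of the samples. For AG1478 against control, 3 of 35 splits reached the real 2 genes (highest other 7) and 2 of 35 the real 8 lists (highest other 8). For HBEGF against control, only the real split (1 of 35) reached 3 genes, the highest other count being 0, so chance is excluded only among splits that ignore the matching of arrays by time. Exchanges of HBEGF and control within time points number only 8, too few to judge, and the count of 3 itself fell to 0 without control at 3 h, control at 8 h or HBEGF at 3 h. Its lists were reached by 22 of 35 splits, with a highest of 7 against the real 2. For HBEGF against pressure only 10 splits exist, too few to judge: 1 of 10 for genes (real 8, highest other 0) and 3 of 10 for lists (real 6, highest other 8). For the time trend all 35 reached the real 0 genes (highest other 5), and 17 of 35 reached the real 3 lists (highest other 9).

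The 26 genes lower at 3 h of pressure may owe that fall to the axis that separates the hybridization batches: their median difference between batch 2 and batch 1 was 0.618, where random lists of the same size stayed below 0.239 in nearly all draws. Loss of 5′ RNA ends in that array is excluded, since its ACTB 3′ to 5′ difference was only 0.047 above that of control at 3 h. This doubt includes EGFR, EIF5A and SLC38A1. Over all genes, the pressure difference correlated with the same batch difference at -0.263 at 3 h and -0.204 at 8 h. The 8 h pair thus lay along this axis too, though its arrays were part of the batch fit. The SRF and actin genes also differed along it. Their median for AG1478 against control at 1 h, across batches, was 0.737 as deposited and 0.165 with the batch effect removed. On the first principal component pressure lay further from batch 2 than control at 3 h (12.2 against 6.18) and 8 h (5.82 against 0.70). At 1 h it did not (-33.8 against -33.1), and the list's median difference under pressure was 0.18. Whether the axis adds to the list's rise was not tested. The separation of the batches was not explained by loss of 5′ ends, as the array of batch 1 with the highest ACTB difference lay 0.8% of the way to batch 2. It was not explained by time of harvest, as the 8 h array of batch 2 lay 78.2% of the way from the 8 h arrays of batch 1 to the early arrays of batch 2.

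The rise of CYP1B1 under AG1478 could come from batch, but the smaller of its differences within batch 1 was 1.345, which excludes that. It was also higher by 1.345 at 3 h and 2.577 at 8 h in pressure with AG1478 against pressure, and at -0.358 at 1 h. Those arrays cross batches at 1 and 8 h but not at 3 h. An action of AG1478 itself fits the value of 3 h. Activation of the aryl hydrocarbon receptor could not be settled: CYP1A1, its classic target, differed by 0.437 at the lower of the 2 times and was too dim to be tested.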
